A study of Mus musculus with 9 samples.

How the data were processed

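Gene expression was measured in 9 libraries from an Eµ-Myc lymphoma, clone 4242, a B-cell lymphoma line from mice that carry a Myc transgene driven by the immunoglobulin heavy chain enhancer. Per the labels, cells were treated for 2 h in biological triplicate with 1 µM JQ1, with 2.5 µM RG6146 or with DMSO, the solvent control. Both compounds are inhibitors of the BET bromodomain proteins, which bind acetylated histones. Per the labels' protocols, 3′ mRNA libraries were made from 500 ng of RNA with the QuantSeq kit, which gives about 1 read per transcript near its polyadenylated end, and were sequenced on a NextSeq 500 as single-end reads of 75 bases.

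The deposited table holds raw counts of reads per gene, not normalised. Per the submitters' processing notes, the authors used bcl2fastq 2.17.1.14, FastQC 0.11.5, cutadapt 1.7, HISAT2 2.1.0, featureCounts of Subread, limma and the mouse build mm10. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads from a gene and from a gene on its opposite strand therefore may not be separated, and reads of near-identical copies may be split or dropped. A 3′ tag counts molecules near the end of a transcript and carries no information on splicing.

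The table has 43629 genes under Ensembl identifiers and 92 ERCC spike-in sequences, synthetic RNAs of known amount. The ERCC rows were kept out of library sizes and tests in the chosen design. Symbols and positions came from the GENCODE M21 annotation of the same build. A symbol was found for 42462 identifiers and not for 1167, which held 1.85% to 2.66% of the gene counts. Total gene counts per library lay between 3410161 and 5031717. The gene with the most counts, Gm42418, which overlaps ribosomal RNA sequence, took 9.95% to 14.6% of them. Replicates of a group differed by more than sampling noise in each of the 9 pairs, with a chi-square per degree of freedom of 6.87 to 17.0, so no library was counted as a repeat of another.

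Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given and its minimum count of 10, which left 11002 genes, 9156 of them protein-coding and 936 processed pseudogenes. Libraries were scaled by TMM. A quasi-likelihood model with robust moderation of the dispersions was fitted to all 9 libraries with the group as its only term, and the 3 comparisons were tested in it with the quasi-likelihood F-test. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes, with no fold threshold. The adjusted p-values of single genes in the text come from this test unless another tool is named. Errors after a log2 fold change are standard errors from this model, and 95% intervals are Wald intervals around the fold change without a prior count, so they are not centred on the log2 fold change given, which uses edgeR's prior count. Levels of single genes are TMM-normalised CPM, counts scaled to the library size, given as mean ± SD over the 3 libraries of a group. Summed levels of marker lists and of myeloid granule transcripts are CPM of the total gene counts without TMM. p-values and intervals describe the spread between cultures of a single clone.

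The comparisons, their tests, the gene lists and the rule for named genes were fixed before the data were examined; robust moderation was not written down then. The rule named 12 genes whatever their result, among them Myc, Hexim1, Serpini1, Cd274, Bcl2, Bcl2l11, Ccr2, Brd2, Brd3, Cdk6 and Il7r. For each compound against DMSO it named the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM over the 6 libraries and with all 3 treated libraries beyond all 3 DMSO libraries. For RG6146 against JQ1 it named the called genes, up to 10 in each direction. From each described list it named up to 4 members with the smallest p. Not all genes that the rule names are described here. Serpini1, Cd274 and Ccr2 had too few counts to test.

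The 26 lists cover BET inhibitor response markers, elongation and BET factors, the MYC network, MYC targets, p53 targets, the BCL2 family, B cell transcription factors, B cell receptor and surface genes, immediate early genes, NF-kappaB targets, interferon response and antigen presentation. They also cover G1/S and G2/M genes, histones, heat shock, the unfolded protein response, cholesterol synthesis, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes as a sign of RNA quality, and markers of T and NK, myeloid, erythroid, and stromal and endothelial cells. Of 686 listed symbols 684 were found, and 28 genes stand in more than 1 list. The 23 lists with at least 5 tested members were tested with camera (limma 3.58.1) against all other tested genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists by Benjamini-Hochberg.

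The fold changes of the compounds share the DMSO libraries. Their correlation was therefore set beside 20 simulations of unchanged groups against the same controls. Fits with separate DMSO libraries for each compound, on the same genes and size factors, were added after the results were seen. The code was tested on simulated counts with 3 sizes of change. In the simulated JQ1 comparison of 10670 genes, 10.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 90.9% of those changed 4-fold were called, and 6.72% of the calls were false. In the simulated RG6146 comparison of 10713 genes these shares were 14.9%, 62.7%, 90.9% and 5.88%. For RG6146 against JQ1, with 10695 genes, they were 7.46%, 58.2%, 92.4% and 8.70%. The simulations changed 67, 67 and 66 genes at these sizes, fewer than were called after either compound, so their adjusted threshold was stricter than in the comparisons with DMSO. For RG6146 against JQ1 the simulation made 115 calls and the data made 1. There the simulated threshold was looser, so its shares may overstate what the direct comparison could detect.

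Alternatives written beforehand were RLE, upper quartile and library size scaling, no count filter, a filter at a mean of 10 CPM, DESeq2 1.42.0, limma-voom, a fit of only the 6 libraries compared, the replicate number as a block, an adjusted p of 0.01, a test against a 1.5-fold change (glmTreat), and each library left out in turn. Alternatives chosen after seeing the data were scaling by the ERCC counts, the same with the replicate block, no robust moderation, protein-coding genes only, and leaving out DMSO replicate 2 and JQ1 replicate 2 together, the libraries with the most Mpo counts. The count filter was redone in each fit of fewer libraries. Without 1 library it kept 11126 to 11391 genes, so the tested members of a list may differ from those of the main fit.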

Results

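Gene expression was measured by 3′ mRNA sequencing in Eµ-Myc lymphoma cells treated for 2 h with JQ1 (1 µM), RG6146 (2.5 µM) or DMSO, with 3 libraries per group. JQ1 is a widely used inhibitor of the BET bromodomain proteins, and RG6146 is a further inhibitor of the same family. The libraries held 3410161 to 5031717 gene counts each: 3410161 to 5003725 under DMSO, 3964732 to 5031717 under JQ1 and 3947240 to 4609612 under RG6146. With 3 libraries per group at these depths, the 95% interval of a log2 fold change of the median gene reached 0.351 to either side. On the first principal component, which held 41.6% of the variance, all 6 treated libraries lay on one side and the 3 DMSO libraries on the other.

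The comparison of JQ1 with DMSO asked which transcripts differ after 2 h of BET inhibition. Tspoap1, which encodes a protein that binds RIM proteins and the TSPO receptor, was the largest rise among the genes named by the rule. It went from 5.22 ± 0.494 CPM (SD, n = 3) under DMSO to 136 ± 2.45 CPM, a log2 fold change of 4.70 ± 0.12 (SE). The largest fall in that set was Il7r, the receptor of interleukin 7, from 31.1 ± 4.96 to 1.79 ± 0.340 CPM, a log2 fold change of -4.09 ± 0.28. Hexim1, an inhibitor of the elongation kinase P-TEFb and a known marker of BET inhibition, rose by 1.55 ± 0.07, and Bcl2l11, which encodes the pro-apoptotic protein BIM, rose by 1.93 ± 0.08. Most tested genes of B cell identity fell, while among histone genes, immediate early genes and genes of transcription elongation more members rose than fell.

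The test called 3184 of 11002 genes after JQ1, 1495 higher and 1689 lower (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 265 were over 2-fold higher and 557 over 2-fold lower. The 3 JQ1 and the 3 DMSO libraries did not overlap for 42.6% of all tested genes, where chance gives 10%. Library size scaling without TMM shifted the median of all genes to -0.13 and the share of higher genes among the calls from 47.0% to 27.2%. Scaling by the ERCC counts alone called 1196 genes, and 37.2% of them were higher. With the replicate number as a block it called 2829, of which 42.6% were higher. Its median of all genes stayed near 0, at -0.0067 without and -0.014 with the block. Over the 3 comparisons ERCC scaling ended 70 of the 202 calls of named genes without the block and 12 with it.

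Next to Tspoap1 (Ensembl gene ENSMUSG00000034156, protein-coding, chromosome 11, 87760541 to 87785928 on mm10), the largest rises were Cnnm4 (3.37 ± 0.24), a magnesium transporter, the histone gene Hist1h2bc (3.03 ± 0.17) and the Wnt receptor gene Fzd5 (2.93 ± 0.26). Zswim6 (2.34) followed, and Habp4 (4.51-fold), Sertad1 (4.50-fold), Sil1 (4.29-fold), which encodes an exchange factor of the endoplasmic reticulum, and Baiap2 (4.28-fold) were also among the 10. The highest adjusted p among the rises given here was that of Fzd5, 1.1e-07. Next to Il7r (chromosome 15, 9505788 to 9530176), the largest falls were the histone deacetylase gene Hdac9 (-3.67 ± 0.32), the kinase gene Mast4 (-3.65 ± 0.21), Gm12481 (-3.62 ± 0.53), the leukotriene receptor gene Cysltr1 (-2.82 ± 0.18) and the corepressor gene Cbfa2t3 (-2.81 ± 0.21). Spata13 (-2.77), the cytokine gene Il16 (-2.63), Jakmip1 (-2.62) and Fam221b (-2.53) followed. The highest adjusted p among these falls was that of Gm12481, 0.00334. Gm12481 is a processed pseudogene that lies inside Fam221b on the opposite strand, so its reads and those of Fam221b may not be separated. Mast4 overlaps Cd180, Cbfa2t3 overlaps Gm20388 and Il16 overlaps Stard5, each on the opposite strand.

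Among the 12 genes named in advance, 9 could be tested, and 7 were called after JQ1 over all tested genes and 8 when adjusted over the list alone. Brd2 rose from 524 ± 85.6 to 1711 ± 53.7 CPM, a log2 fold change of 1.71 ± 0.23 (adjusted p = 0.00227). Brd3 had -0.05 ± 0.08 (adjusted p = 0.691). Bcl2, an anti-apoptotic gene, fell by 0.47 on the log2 scale (adjusted p = 6.2e-04; with ERCC scaling -0.48 and 0.199, and with the replicate block added 0.00130), and Cdk6, a kinase of G1 phase, fell by 0.90 (adjusted p = 0.00291). Myc rose by 0.42 ± 0.11, from 114 ± 11.1 to 152 ± 22.8 CPM (adjusted p = 0.00815). Its call ended with library size scaling (0.28 ± 0.11, adjusted p = 0.0603), with ERCC scaling (0.43 ± 0.23, 0.276, but 0.39 and 0.0260 with the replicate block) and without DMSO replicate 2 and JQ1 replicate 2 (0.31 ± 0.12, 0.0922), and in the test against a 1.5-fold change (1).

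Of 34 tested B cell receptor and surface genes, 23 fell and 0 rose after JQ1 (27 and 1 adjusted over the list alone), with a median log2 fold change of -1.11. They included Cd22 (-2.05), Fcrla (-1.68) and the signalling adaptor gene Blnk (-1.22). Of 28 B cell transcription factors, 18 fell and 2 rose (20 and 3 adjusted over the list alone), with a median of -0.60. Ikzf1 (-1.59), Pou2f2 (-1.36), Mef2c (-1.32) and Ebf1 (-0.80), regulators of B cell development, were among those that fell. Both lists stood below other genes with the preset correlation (camera adjusted p = 2.7e-12 and 1.6e-06) and with an estimated correlation (adjusted p = 0.0256 and 0.0235). Summed markers of myeloid cells were also lower in these groups, at 427 ± 294 CPM under DMSO and 145 ± 114 CPM under JQ1 (exact permutation p = 0.2, two-sided, n = 3 against 3, smallest possible 0.1). Stromal and endothelial markers summed to 137 ± 6.53 CPM under DMSO and 100.5 ± 0.722 CPM under JQ1. T and NK cell markers summed to 11.7 ± 1.76 and 6.14 ± 2.82 CPM (exact permutation p = 0.1 for both sums, the smallest possible). These sums are without TMM, whose factors of 1.04 to 1.07 under DMSO and 0.948 to 0.977 under JQ1 would narrow the gaps. Vim was 1 of the 2 tested stromal and endothelial genes. With TMM it was at 97.6, 105 and 99.0 CPM under DMSO and 96.2, 92.6 and 96.5 CPM under JQ1. Pecam1, the other, fell. Cd2 was the only tested T and NK cell gene and made up much of that sum. With TMM it was at 7.71, 9.95 and 5.51 CPM under DMSO and 3.58, 3.09 and 2.35 CPM under JQ1.

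Of 33 histone genes, 14 rose and 0 fell after JQ1 (16 and 0 adjusted over the list alone), among them H3f3b (2.04), Hist2h2be (1.99) and H2afx (0.99). The libraries read polyadenylated ends, so a change in the polyadenylation of histone transcripts cannot be told from a change in their amount. Of 22 immediate early genes, which respond to signals without new protein synthesis, 11 rose and 4 fell (11 and 4 adjusted over the list alone), with Jund (1.68), Jun (1.58), Ier5 (1.30) and Btg1 (1.13) among the rises. Of 29 elongation and BET factors, 11 rose and 2 fell (14 and 4 adjusted over the list alone). They included Polr2a (1.28), the largest subunit of RNA polymerase II, and the PAF1 complex genes Paf1 (1.06) and Ctr9 (0.96). Of 22 genes of the unfolded protein and integrated stress response, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Ppp1r15a (1.21), Hspa5 (0.97), Mthfd2 (0.79) and Atf4 (0.72). The camera adjusted p-values of these 4 lists were 3.4e-05, 1.2e-04, 4.0e-04 and 0.00298, and with an estimated correlation 0.0429, 0.0429, 0.0339 and 0.0429. ERCC scaling gave 6 rises and 0 falls among elongation and BET factors (10 and 2 with the replicate block) and 1 rise and 10 falls among B cell transcription factors (2 and 18). Library size scaling gave 10 and 5 for the former, with a median of 0.09 instead of 0.22, and 2 and 20 for the latter.

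Another 4 lists stood above other genes after JQ1 with the preset correlation only. Of 22 genes of cholesterol synthesis, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with Insig1 (1.24), Hsd17b7 (1.11) and Hmgcs1 (0.68). Their camera adjusted p was 4.0e-04, and the adjusted p was 0.113 with an estimated correlation. Of 52 cytosolic ribosomal protein genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone) by small amounts, such as 0.40 for Rplp1 and 0.31 for Rplp2 (adjusted p = 0.00318, and adjusted p = 0.193 with an estimated correlation). With library size scaling 4 of them rose and the median was 0.01 instead of 0.15, and with ERCC scaling 0 rose, or 5 with the replicate block. Of 19 heat shock genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with Dnajb1 (0.64), Stip1 (0.52) and Hspa8 (0.41) (adjusted p = 0.0234, and adjusted p = 0.193 with an estimated correlation). With a mean of at least 10 CPM the preset value of the heat shock list was 0.162. Of 10 genes of the MYC network, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Mxd1 (1.63) and Mlxip (0.50). Its adjusted p was 0.0342, and the adjusted p was 0.126 with an estimated correlation. The call of the MYC network also ended with library size scaling (0.0515), with a mean of at least 10 CPM (0.0839) and without DMSO replicate 3 (0.0556). With library size scaling the rises and falls were 4 and 2 for heat shock and 3 and 2 for the MYC network. ERCC scaling gave 0 and 0 for heat shock (6 and 1 with the replicate block), 1 and 0 for the MYC network (4 and 0) and 4 and 0 for cholesterol synthesis (9 and 1).

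The other 13 tested lists were not called after JQ1 by camera. Camera tests a shift of a list in 1 direction. It therefore says little on lists whose members move both ways, such as BET inhibitor response markers and the BCL2 family. Of 44 MYC targets in growth and nucleotide synthesis, 12 fell and 7 rose (13 and 7 adjusted over the list alone), with the folate carrier gene Slc19a1 (2.00-fold lower), Ppan (-0.69), Gnl3 (-0.50) and Dkc1 (-0.50) (adjusted p = 0.476). Of 9 BET inhibitor response markers, 5 fell and 3 rose, the same numbers as when adjusted over the list alone, with Zmynd8 (-1.80) beside Il7r and Hexim1 (adjusted p = 0.223). Of 20 p53 targets, 5 rose and 0 fell over all genes and adjusted over the list alone, with Sesn2 (1.52), Ddit4 (1.07), Xpc (0.73) and Btg2 (0.54) (adjusted p = 0.179). The BCL2 family had 2 rises and 2 falls in 13 genes by both adjustments, with Bmf (-1.37) beside Bcl2 and Bcl2l11 (adjusted p = 0.855). Of 39 G1 and S phase genes, 6 rose and 8 fell by both adjustments, with Slbp (1.00), Cdkn2d (0.73), Ccnd1 (-0.55) and Rrm2 (0.49) (adjusted p = 0.793). Of 30 G2 and M phase genes, 2 rose and 3 fell by both adjustments (adjusted p = 0.608), and 6 of 18 glycolysis genes rose and 1 fell by both, with the glucose transporter genes Slc2a1 (0.95) and Slc2a3 (-1.07) moving apart (adjusted p = 0.223). With library size scaling, which shifts all genes down, the rises and falls after JQ1 were 0 and 12 for G2 and M phase, 5 and 15 for G1 and S phase, 5 and 5 for p53 targets, 4 and 16 for MYC targets and 2 and 1 for glycolysis. With ERCC scaling they were 0 and 0 for G2 and M phase, 2 and 1 for G1 and S phase, 4 and 0 for p53 targets, 0 and 2 for MYC targets and 1 and 1 for glycolysis, and with the replicate block added 0 and 2, 5 and 7, 5 and 0, 4 and 10, and 3 and 1.

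Of 32 nuclear genes of oxidative phosphorylation, 4 rose and 0 fell after JQ1 (3 and 0 adjusted over the list alone), with Ndufb10 at 0.48 (adjusted p = 0.144, and 0.0453 without DMSO replicate 3). Library size scaling gave 1 rise and 2 falls, and ERCC scaling 0 calls. Of 13 NF-kappaB targets, 3 fell and 1 rose by both adjustments, with Birc3 (-0.97), Nfkb1 (-0.94) and Tnfaip8 (-0.93) (adjusted p = 0.179). That list passed without RG6146 replicate 1 (0.0482), without DMSO replicate 2 (0.00615) and without DMSO replicate 2 and JQ1 replicate 2 (0.00926). Of 12 interferon response genes, 3 fell and 1 rose (3 and 2 adjusted over the list alone), with Irf2 at -1.14. The median of that list was 0.05, while its mean was -0.24 and its test pointed down (adjusted p = 0.476). Of 15 antigen presentation and checkpoint genes, 3 fell and 2 rose by both adjustments, with Cd47 at -0.71 (adjusted p = 0.105). Without a library this list passed at 0.0328 (JQ1 replicate 1), 0.00136 (JQ1 replicate 2), 0.0395 (JQ1 replicate 3), 0.0136, 0.0131 and 0.0158 (RG6146 replicates 1, 2 and 3) and 4.5e-04 (DMSO replicate 2), and at 2.8e-05 without DMSO replicate 2 and JQ1 replicate 2. The count filter was redone without each library and kept 11126 to 11391 genes instead of 11002. The tested members of a list may therefore differ there, and the change of its p-value cannot be credited to the library alone. In the interferon list and in the antigen presentation list alike, 0 rose and 4 fell with library size scaling. Of 15 mitochondrially encoded genes, 0 were called by edgeR by either adjustment after JQ1. Their median was 0.01 and their camera test pointed up, while their mean lay just below 0 (adjusted p = 0.721). Of 9 myeloid markers 1 rose and 0 fell by both adjustments (adjusted p = 0.224), and the list passed downwards without JQ1 replicate 2 (0.0332), with the replicate block (0.0348) and with ERCC scaling and the block (0.0275). The lists of T and NK cell, stromal and endothelial, and erythroid markers had 1, 2 and 0 tested genes, and of these Cd2 (-1.33) and Pecam1 (-1.75) fell. Whether their transcripts came from other cells or from the lymphoma cells was not tested.

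**Figure D1:**
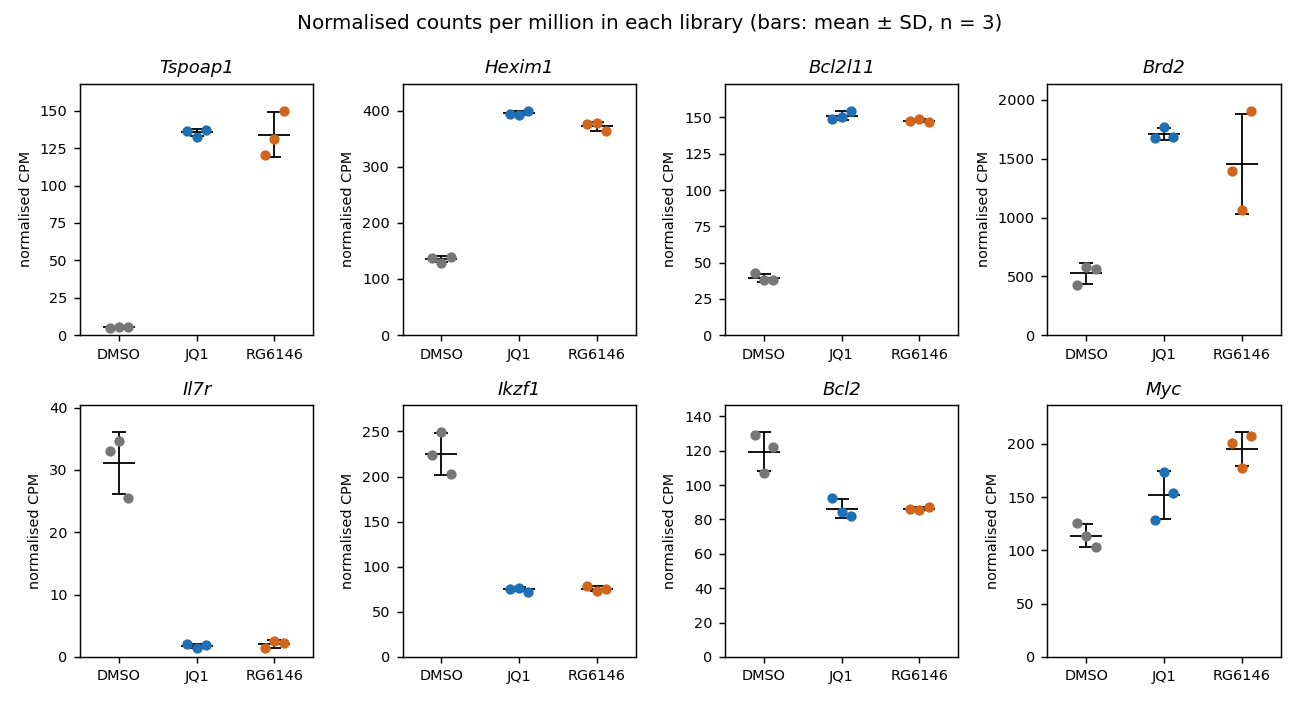
TMM-normalised CPM of 8 genes in each library, on linear axes from 0, with points for the 3 libraries of each group and bars for the mean and SD. Tspoap1, Hexim1, Bcl2l11 and Brd2 were higher and Il7r, Ikzf1 and Bcl2 lower in every treated library than in every DMSO library, and Myc rose from 114 CPM to 152 and 195 CPM.

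The comparison of RG6146 with DMSO asked the same of RG6146 at 2.5 µM. Tspoap1 again led the rises named by the rule, at 121, 131 and 150 CPM in its 3 libraries and a log2 fold change of 4.68 ± 0.12, and Il7r led the falls, at 2.06 ± 0.610 CPM and -3.91 ± 0.27. Hexim1 rose by 1.46 ± 0.07 and Bcl2l11 by 1.90 ± 0.08. Most tested B cell receptor and transcription factor genes fell, and among histone genes, immediate early genes and elongation factor genes more members rose than fell. The test called 2863 genes, 1374 higher and 1489 lower, of which 246 and 513 changed by over 2-fold (edgeR quasi-likelihood test). Groups did not overlap for 40.9% of genes, where chance gives 10%. With library size scaling the median of all genes was -0.10 and the share of higher genes among the calls 29.7% against 48.0%. DESeq2 called 1902 genes, and ERCC scaling called 1082 without and 2604 with the replicate block. Of these, 42.3% and 50.8% were higher, and the medians of all genes were 0.041 and 0.035.

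Other large rises after RG6146 were Cnnm4 (3.28 ± 0.24), Hist1h2bc (3.22 ± 0.17), Fzd5 (2.83 ± 0.27), Zswim6 (2.20), Baiap2 (2.12), Gm4202 (2.12 ± 0.37), Sil1 (2.09) and Habp4 (2.09). Gm4202 is a processed pseudogene (adjusted p = 0.00128). The other large falls were Mast4 (-3.66 ± 0.21), Gm12481 (-3.61 ± 0.53), Il16 (-3.11 ± 0.20), Cbfa2t3 (-3.01 ± 0.22), Hdac9 (-2.83 ± 0.27), Jakmip1 (-2.83), Cysltr1 (-2.78), 3425401B19Rik (-2.73) and Kctd14 (-2.67). The overlaps of Gm12481, Mast4, Cbfa2t3 and Il16 with genes on the opposite strand apply here too.

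Of the 9 tested genes named in advance, 7 were called after RG6146 over all genes and 7 adjusted over the list alone. Brd2 rose to 1457 ± 425 CPM, with a spread between libraries (1395, 1067 and 1910 CPM) larger than under JQ1, and a log2 fold change of 1.47 ± 0.23 (adjusted p = 0.00464). Brd3 was not called (-0.06 ± 0.08, adjusted p = 0.662). Bcl2 fell by 0.47 (adjusted p = 6.8e-04; with ERCC scaling -0.43 and 0.294, and with the replicate block added 0.00348). Cdk6 fell by 0.65 (adjusted p = 0.0232), a call that ended with DESeq2 (0.0671), with ERCC scaling (0.154), without robust moderation (0.0527), without RG6146 replicate 1 (0.111) or 3 (0.106) and without DMSO replicate 1 (0.0650), 2 (0.0552) or 3 (0.0602), or DMSO replicate 2 together with JQ1 replicate 2 (0.0814). The log2 fold change in these settings lay between -0.66 and -0.50, and ERCC scaling with the replicate block kept the call (0.0321). Myc rose by 0.78 ± 0.11, to 195 ± 15.6 CPM (adjusted p = 5.9e-05), and its call ended only in the test against a 1.5-fold change (0.169) among 25 alternatives.

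Of 34 B cell receptor and surface genes, 23 fell and 1 rose after RG6146 (25 and 1 adjusted over the list alone), with a median of -1.03, including Cd22 (-1.68), Fcrla (-1.54) and Tnfrsf13b (-1.02). Of 28 B cell transcription factors, 17 fell and 2 rose (19 and 2 adjusted over the list alone), with Ikzf1 (-1.57), Pou2f2 (-1.33), Mef2c (-1.25) and Ikzf3 (-1.17). Their camera adjusted p-values were 4.0e-12 and 9.1e-08, and 0.0307 and 0.0144 with an estimated correlation. Summed myeloid markers were at 121 ± 19.4 CPM under RG6146 (exact permutation p = 0.1 against DMSO, two-sided, n = 3 against 3, the smallest possible), stromal and endothelial markers at 108 ± 3.70 CPM and T and NK cell markers at 6.46 to 8.68 CPM (exact permutation p = 0.1 for both). These sums too are without TMM. With TMM, the stromal marker gene Vim was at 102, 96.2 and 101 CPM under RG6146, while Pecam1 fell. Cd2, the only tested T and NK cell gene, was at 3.88, 5.31 and 5.23 CPM. Of 33 histone genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone), with H3f3b (2.02), Hist2h2be (1.83) and H2afx (1.00). Here too only polyadenylated histone transcripts were read. Of 22 immediate early genes, 12 rose and 1 fell (13 and 2 adjusted over the list alone), with Jund (1.52), Jun (1.41), Ier5 (2.15-fold) and Btg1 (2.14-fold). Of 29 elongation and BET factors, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with Polr2a (1.21), Paf1 (1.00) and Ctr9 (0.96). The camera adjusted p-values of these 3 lists were 2.7e-06, 4.4e-05 and 0.00179, and 0.0391, 0.0462 and 0.0403 with an estimated correlation. ERCC scaling gave 6 rises and 0 falls for elongation and BET factors (10 and 2 with the replicate block) and 0 and 9 for B cell transcription factors (2 and 16). Library size scaling gave 9 and 4 for the former, with a median of 0.09 instead of 0.20, and 1 and 19 for the latter.

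Of 22 genes of the unfolded protein and integrated stress response, 9 rose and 1 fell after RG6146 (10 and 1 adjusted over the list alone), with Hspa5 (0.88), Mthfd2 (0.71) and Atf4 (0.67). The camera adjusted p was 0.00646, and the adjusted p was 0.0552 with an estimated correlation. Its call ended at a mean of at least 10 CPM (0.0667). Of 22 cholesterol synthesis genes, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with Insig1 (1.31) and Sqle (0.55) (adjusted p = 0.00354, and adjusted p = 0.158 with an estimated correlation). Of 19 heat shock genes, 7 rose and 1 fell by both adjustments, with Stip1 (0.47), Dnajb1 (0.41), Hspa8 (0.36) and Chordc1 (-0.42) (adjusted p = 0.0378, and adjusted p = 0.228 with an estimated correlation). The heat shock call ended with library size scaling (0.0569), ERCC scaling with the replicate block (0.0539) and a mean of at least 10 CPM (0.253), and without RG6146 replicate 1 (0.0578) or DMSO replicate 1 (0.0644). Of 52 cytosolic ribosomal protein genes, 6 rose and 0 fell by both adjustments, with Rpl7a at 0.34 (adjusted p = 0.0267, and adjusted p = 0.307 with an estimated correlation). With library size scaling 1 rose, and with ERCC scaling 0, or 5 with the replicate block. ERCC scaling gave 1 rise and 0 falls for heat shock (7 and 1 with the block), 4 and 0 for cholesterol synthesis (9 and 1) and 2 and 0 for the MYC network (4 and 0). The camera call of the ribosomal list ended with library size scaling (0.149), ERCC scaling with the replicate block (0.0618) and a mean of at least 10 CPM (0.112). The MYC network had 4 rises and 0 falls in 10 genes (4 and 1 adjusted over the list alone), with Mxd1 (1.37) and Mlxip (0.49) beside Myc. Its adjusted p was 0.0523, and 0.0417 without JQ1 replicate 1, 0.0387 without JQ1 replicate 2, 0.0429 without JQ1 replicate 3, 0.0480 and 0.0418 without RG6146 replicates 1 and 2, 0.0479 and 0.0494 without DMSO replicates 1 and 2, and 0.0449 without DMSO replicate 2 and JQ1 replicate 2.

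The remaining lists were not called after RG6146 by camera, with the same limit for lists whose members move both ways. MYC targets had 9 falls and 6 rises in 44 genes (12 and 6 adjusted over the list alone), with Ppan (-0.75), Slc19a1 (-0.73), Wdr43 (-0.48) and Dkc1 (-0.47). Their median was 0.03, while their mean was -0.09 and the test pointed down (adjusted p = 0.449). BET inhibitor response markers had 5 falls and 3 rises in 9 genes by both adjustments, with Zmynd8 at -1.64 (adjusted p = 0.291). Of 20 p53 targets, 4 rose by both adjustments, with Sesn2 (1.41), Ddit4 (0.81), Xpc (0.61) and Btg2 (0.57) (adjusted p = 0.209). The BCL2 family had 1 rise and 2 falls in 13 genes by both, with Bmf at -1.76 (adjusted p = 0.870). G1 and S phase genes had 6 rises and 8 falls in 39 (7 and 9 adjusted over the list alone), with Slbp (1.11), E2f2 (-0.64), Ccnd1 (-0.60) and Mcm3 (-0.40) (adjusted p = 0.554). G2 and M phase genes had 2 rises and 6 falls in 30 by both, with Foxm1 (-0.66) and Plk1 (-0.47) (adjusted p = 0.278). Glycolysis had 5 rises and 1 fall in 18 by both, with Slc2a1 at 0.92 (adjusted p = 0.291). With library size scaling the rises and falls after RG6146 were 0 and 9 for G2 and M phase, 4 and 13 for G1 and S phase, 4 and 3 for p53 targets, 3 and 16 for MYC targets and 3 and 1 for glycolysis. With ERCC scaling they were 0 and 0, 1 and 0, 2 and 0, 0 and 2, and 1 and 0 in the same order, and with the replicate block added 0 and 3, 7 and 7, 6 and 0, 4 and 7, and 4 and 1.

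Of 32 nuclear genes of oxidative phosphorylation, 3 rose after RG6146 over all genes and 0 adjusted over the list alone (adjusted p = 0.209 by camera). Library size scaling gave 0 rises and 1 fall, and ERCC scaling 0 calls. NF-kappaB targets had 3 falls and 0 rises in 13 genes by both adjustments, with Tnfaip8 (-1.07), Nfkb1 (-0.94) and Birc3 (-0.88) (adjusted p = 0.129). They passed with a mean of at least 10 CPM (0.0382) and without RG6146 replicate 3 (0.0156) or DMSO replicate 2 (0.00639), and without DMSO replicate 2 and JQ1 replicate 2 (0.00814). Interferon response had 2 falls and 1 rise in 12 genes by both, with Irf2 at -1.22 (adjusted p = 0.365). Antigen presentation had 3 falls and 2 rises in 15 genes by both, with H2-Ob (-1.07) and Cd47 (-0.82) (adjusted p = 0.128). Without a library this list passed at 0.0161, 0.0180 and 0.0225 (JQ1 replicates 1, 2 and 3), 0.0306 and 0.0180 (RG6146 replicates 2 and 3) and 7.5e-04 (DMSO replicate 2), and at 4.7e-04 without DMSO replicate 2 and JQ1 replicate 2. Here too the count filter was redone without each library, so the tested members of a list may differ from those of the main fit. In the interferon list and in the antigen presentation list alike, 0 rose and 3 fell with library size scaling. The mitochondrially encoded genes had 0 calls in 15 by edgeR and a median of 0.15 (adjusted p = 0.209), and myeloid markers had 1 rise and 0 falls in 9 and a median of -1.73 (adjusted p = 0.346), each by both adjustments. Pecam1 fell by 1.69 on the log2 scale, and Cd2 had -0.67 (adjusted p = 0.0855).

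**Figure D2:**
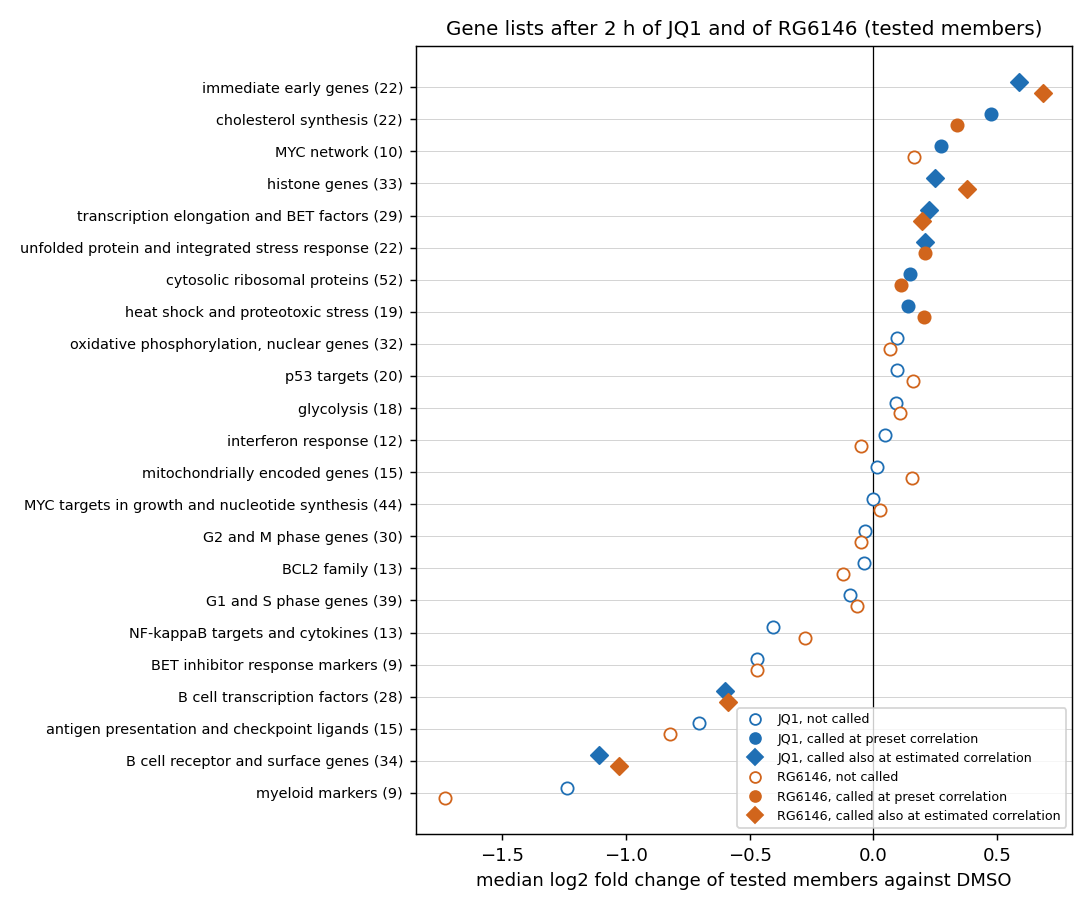
Median log2 fold change of the tested members of each list after JQ1 (blue) and RG6146 (orange) against DMSO, with the number of tested members in parentheses; filled symbols passed camera with the preset correlation and diamonds also with an estimated one. B cell receptor and surface genes lay at -1.11 and -1.03 and immediate early genes at 0.59 and 0.68, while with library size scaling the medians of p53 targets, interferon response and mitochondrially encoded genes after JQ1, of MYC targets after RG6146, and of glycolysis and oxidative phosphorylation after both compounds changed from above to below 0.

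Most calls were shared by the compounds. Of the genes called higher, 1144 were called after both compounds, 83.3% of those called after RG6146, where independent lists would share 187. Of the genes called lower, 1275 were shared, 85.6%, where independent lists would share 229. Called in opposite directions were 0 genes by edgeR. Tspoap1, Cnnm4, Hist1h2bc, Fzd5, Zswim6, Habp4, Sil1 and Baiap2 stood among the 10 largest rises after each compound, and Il7r, Hdac9, Mast4, Gm12481, Cysltr1, Cbfa2t3, Il16 and Jakmip1 among the 10 largest falls. Across the 11002 genes, which are not independent replicates, the correlation of the fold changes was 0.875, against 0.506 in 20 simulations of unchanged groups that share the DMSO libraries (highest 0.523). The covariance was 0.366 against 0.0537, a difference of 0.312, and the simulations called 0.15 genes in both comparisons on average against the observed 2419. The slope of RG6146 on JQ1 was 0.978 with the simulated covariance and the simulated variance of the JQ1 fold changes subtracted as noise. The correlation, with the simulated variance of RG6146 subtracted too, was 1.0009. A correlation cannot exceed 1, so the subtraction is inexact. The noise was simulated only for the main fit of all libraries and 11002 genes, and the same amount was removed in other settings. There the slope was 0.585 with no count filter and 0.812 without JQ1 replicate 2. It was 0.831 without DMSO replicate 2 and JQ1 replicate 2, and 1.06 with a mean of at least 10 CPM. Noise in the JQ1 fold changes that is not removed lowers the slope. The lower values therefore cannot show whether RG6146 had a weaker effect. With 1 DMSO library as the control of 1 compound and the other 2 as that of the other, the 6 possible splits gave covariances of 0.306 to 0.321 (simulated mean 0.00312) and correlations of 0.611 to 0.647. Shared calls in these splits were 512 to 621 higher genes, where independent lists would share 69.1 to 105, and 599 to 750 lower genes, against 91.7 to 129. No split leaves 2 DMSO libraries for each compound, so in the full comparison part of the excess of shared calls over independent lists may come from the shared controls.

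**Figure D3:**
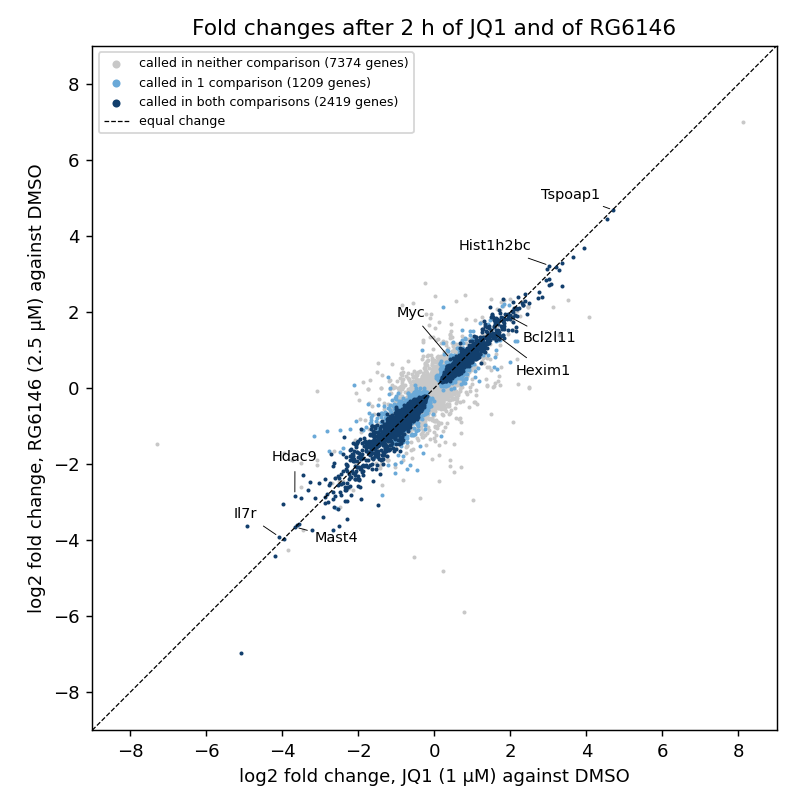
Log2 fold change of each of the 11002 tested genes after JQ1 (1 µM, horizontal axis) and RG6146 (2.5 µM, vertical axis) against DMSO. Colours give the number of comparisons in which a gene was called, and the dashed line marks equal change; 2419 genes were called after both compounds and 0 of them in opposite directions.

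The direct comparison of RG6146 with JQ1 asked whether the compounds differ in effect at the doses used, 2.5 and 1 µM, which are not matched. Gm12693, a processed pseudogene on chromosome 4 (94935621 to 94936103), was the single gene called, at 12.8 ± 1.68 CPM under RG6146 and 4.43 ± 0.621 CPM under JQ1, a log2 difference of 1.51 ± 0.23 (edgeR adjusted p = 0.0321). It was higher in all 3 RG6146 libraries than in all 3 JQ1 libraries. Its sequence is 99.8% identical to the Rwdd1 transcript over 473 bases, so its reads are uncertain. Its call ended with DESeq2 (0.0523), limma-voom (0.164), the 6 libraries alone (0.0620), no robust moderation (0.327) and the replicate block (0.106). It also ended without JQ1 replicate 1 (0.0509), 2 (0.222) or 3 (0.305), RG6146 replicate 1 (0.162) or 2 (0.102), or DMSO replicate 2 (0.0685) or 3 (0.0508), while the log2 difference stayed between 1.41 and 1.62 without each of the 9 libraries.

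At an unadjusted p under 0.05 there were 427 genes between RG6146 and JQ1, where chance gives 550, and the libraries of the groups did not overlap for 9.93% of genes, where chance gives 10%. DESeq2 called 1 gene, which was not Gm12693, and limma-voom 0. Among 3628 genes called after either compound, the 95% interval of the difference lay within 1.5-fold for 2463 (67.9%) and within 2-fold for 3199 (88.2%), reaching a median of 0.293 to either side on the log2 scale. It excluded 0 for 237 of them (6.53%). For 2177 genes (60.0%) the change was smaller after RG6146. These genes were chosen by calls in the same data, 3184 after JQ1 and 2863 after RG6146. A call favours a large estimate for its compound, so this share does not show a weaker effect of RG6146.

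Myc was higher after RG6146 than after JQ1 by 0.36 (95% interval 0.14 to 0.59), with an adjusted p of 0.999 over all genes and 0.0344 adjusted over the list alone. Of the 9 tested genes named in advance, 0 were called over all genes by edgeR and 1 adjusted over the list alone. The value adjusted over the list alone rose above 0.05 without JQ1 replicate 1 (0.264) or 3 (0.101), RG6146 replicate 1 (0.157) or 3 (0.118), or DMSO replicate 2 (0.0596). It also did so with the replicate block (0.103), no robust moderation (0.113) and ERCC scaling (0.832), and in the test against a 1.5-fold change. Differences with intervals that included 0 were -0.09 for Hexim1 (-0.23 to 0.05), -0.03 for Bcl2l11 (-0.20 to 0.13), -0.23 for Brd2 (-0.78 to 0.32), 0.25 for Cdk6 (-0.19 to 0.70) and 0.18 for Il7r (-0.54 to 0.91). That of Bcl2 was 0.00 at 2 decimals (-0.19 to 0.19).

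Of 23 tested lists, 0 differed between RG6146 and JQ1 by camera, with the preset or an estimated correlation. The smallest adjusted p was 0.379, shared by B cell receptor and surface genes (median difference 0.09), G2 and M phase genes (-0.03), cholesterol synthesis (-0.11), cytosolic ribosomal proteins (-0.03) and mitochondrially encoded genes (0.11). Median and mean differed in sign for BET inhibitor response markers, MYC targets, the BCL2 family, immediate early genes, interferon response, antigen presentation and glycolysis. The test of the BCL2 family, NF-kappaB targets, interferon response and immediate early genes pointed down against means of 0.08, 0.25, 0.06 and 0.01, and that of myeloid markers and BET inhibitor response markers pointed up against means of -0.27 and -0.04. Adjusted over the list alone, BET inhibitor response markers and the MYC network had 1 higher gene each, Myc, and the other lists 0. Antigen presentation and myeloid markers passed without JQ1 replicate 2 (0.0194 for both), and mitochondrially encoded genes without JQ1 replicate 3 (0.0119). Leaving out DMSO replicate 2 and JQ1 replicate 2 together, B cell receptor and surface genes (0.0344), antigen presentation (0.00704) and myeloid markers (0.0114) passed. The count filter was redone in these fits, so the tested members may differ from those of the main fit.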

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

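The test of the copies of Gm12693, the tests of leaving out 1 library for Gm12693, the scaling tests of Myc and all tests of myeloid transcripts were chosen only after the result was seen, and so were ERCC scaling and the joint omission of DMSO replicate 2 and JQ1 replicate 2.

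A difference between the compounds was seen for Gm12693, at a log2 difference of 1.51 between RG6146 and JQ1, and for Myc, at 0.36. The doses differ, so neither is a comparison at matched exposure. For Gm12693, a test of the difference passed over all genes, and for Myc only when adjusted over the list alone. In a fit of the 6 JQ1 and RG6146 libraries by edgeR the real split into 3 and 3 called 0 genes, so all 10 splits called as many by construction, which says nothing on the compounds. The highest other split called 34 genes, with JQ1 replicates 1 and 3 and RG6146 replicate 3 against the rest. The second principal component of all 9 libraries, with 10.9% of the variance, parted the same libraries. JQ1 replicates 1 and 3 and RG6146 replicate 3 lay at 14.6, 21.5 and 7.77. JQ1 replicate 2 and RG6146 replicates 1 and 2 lay at -27.1, -3.08 and -17.2. This may point to a structure of the samples other than the compounds, whose source was not tested. At an unadjusted p under 0.05 the fit of 9 libraries had 427 genes. For JQ1 against DMSO 1 of 10 splits, the real one, called as many as the real 3053 genes, and the highest other called 1. For RG6146 against DMSO it was again 1 of 10, with 2766 genes in the real split and 1 in the highest other. With 10 splits the share is never under 0.1.

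Myc was higher after both compounds than after DMSO, by 0.42 ± 0.11 after JQ1 and 0.78 ± 0.11 after RG6146 (SE, n = 3). Scaling and single libraries as the cause are argued against for RG6146, whose lowest log2 fold change over 5 other scalings was 0.67 and whose highest adjusted p without 1 library was 8.3e-04. After JQ1 the lowest was 0.28 ± 0.11, with library size scaling, where the call ended because the fold was smaller (adjusted p = 0.0603), and ERCC scaling ended it at 0.43 ± 0.23 because the spread was larger (adjusted p = 0.276), but not with the replicate block added (0.39, adjusted p = 0.0260). The highest adjusted p without 1 library was 0.0421, and without DMSO replicate 2 and JQ1 replicate 2 the call ended at 0.31 ± 0.12 (adjusted p = 0.0922), with a smaller fold and fewer libraries. Whether the transgene or the endogenous gene may give the measured rise stays open and was not tested.

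Gm12693 was at 12.8 ± 1.68 CPM after RG6146 and 4.43 ± 0.621 CPM after JQ1 (SD, n = 3), and against DMSO it was at 0.29 ± 0.20 after RG6146 (adjusted p = 0.324) and -1.23 ± 0.23 after JQ1 (adjusted p = 5.7e-04). The summed counts of its near-identical copies had a log2 difference between RG6146 and JQ1 of 0.10 (95% interval -0.06 to 0.26). Reads moved between them and Gm12693 at a fixed total would need -0.11. But the total of Gm12693 and its copies was itself higher after RG6146, by 0.19 (95% interval 0.03 to 0.35). The total was thus not fixed, and the test cannot decide whether reads moved. A single library that carries the difference is argued against, since the log2 difference was 1.41 to 1.62 without each of the 9, although the adjusted p rose to as much as 0.305 with fewer libraries and was below 0.05 only without RG6146 replicate 3 (0.0256) or DMSO replicate 1 (0.0215). An effect of dose stays open.

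Transcripts of myeloid granules (Mpo, Prtn3, Elane and Ctsg, of which Prtn3 was not on the fixed list) differed 33.8-fold between libraries, from 8.07 CPM in JQ1 replicate 3 to 272 CPM in DMSO replicate 2. These are CPM of the total gene counts without TMM. Treatment alone is argued against by the DMSO libraries, whose highest value was 5.75 times the lowest (47.4, 272 and 48.5 CPM). Replicate 2 was the highest in each group, at 121 CPM under JQ1 and 53.7 CPM under RG6146. Within each replicate number the DMSO library was the highest, so a part of the treatment beside another source stays open. Different amounts of 1 other cell type or of its reads are consistent with the share of Mpo, 56.9% to 78.1% of the 4 genes, which was not shown to differ between libraries (permutation chi-square p = 0.207, 100000 simulated tables). A single source of fixed composition for all myeloid transcripts is argued against by S100a8 and S100a9, whose ratio to the granule transcripts ran from 0.849 to 5.66 (permutation chi-square p = 1e-05, the smallest the tables can give), with a chi-square per degree of freedom of 53.1 against at most 17.0 between replicates over all genes, although these p-values cover counting error only and the same test also parted S100a8 from S100a9 (p = 4.5e-04, chi-square per degree of freedom 3.53). Whether these transcripts may come from other cells, from reads of other libraries or from the lymphoma cells themselves stays open, and 9 of the 19 listed markers had enough counts to test.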

How the results depend on the processing

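ERCC scaling with and without the replicate block, no robust moderation, protein-coding genes only and the joint omission of DMSO replicate 2 and JQ1 replicate 2 were chosen only after the data were seen. Of 202 called gene results, 104 were called with the same direction in all 25 alternatives, 98 lost the call in at least 1 and 0 reversed. Of those 98, 66 lost it only with a stricter threshold, ERCC scaling or left-out libraries. ERCC scaling ended 70 of the calls and 12 with the replicate block, library size scaling 22, DESeq2 15 and limma-voom 1.

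Genes called after JQ1 numbered 1977 at an adjusted p of 0.01, 599 in the test against a 1.5-fold change and 1196 with ERCC scaling, and 2492 to 3248 without 1 library. After RG6146 there were 1902 with DESeq2, 1784 at an adjusted p of 0.01, 532 in the test against a 1.5-fold change and 1082 with ERCC scaling, and 2239 to 2970 without 1 library. The stricter thresholds lower the counts by construction, and for DESeq2 the cause was not tested. With the replicate block added, ERCC scaling called 2829 and 2604 genes. The log2 ratio of ERCC counts to library size went with the replicate number in each group, at -6.11, -6.43 and -6.54 under DMSO and -6.16, -6.40 and -6.60 under RG6146 for replicates 1, 2 and 3, and the block takes up such a difference. Between RG6146 and JQ1 there were 17 genes with no count filter and 4 with ERCC scaling, and 0 to 2 without 1 library. There were 0 with a mean of at least 10 CPM, limma-voom, the 6 libraries alone, the replicate block, an adjusted p of 0.01, the test against a 1.5-fold change, no robust moderation, protein-coding genes only and without DMSO replicate 2 and JQ1 replicate 2. At an unadjusted p under 0.05 there were 427 by edgeR, and DESeq2 called 1. The cause of the differences was not tested. The correlation of the fold changes was 0.605 with no count filter, which adds genes with few counts, and 0.841 to 0.885 without 1 library.

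Lists called were 6 after JQ1 and 5 after RG6146 with an estimated correlation. Without 1 library they were 10 to 12, 9 to 12, and 0 to 2 between RG6146 and JQ1, and 3 of the latter without DMSO replicate 2 and JQ1 replicate 2. Fits of fewer libraries also redid the count filter, so the tested members of a list may differ there. The cause was not tested.

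Values that changed sign belonged to results that were not called. Brd3 without 1 library ran from -0.13 to 0.0082 after JQ1 and from -0.14 to 0.0021 after RG6146. Between RG6146 and JQ1, Bcl2 was 0.025 with library size scaling, 0.0094 with upper quartile scaling, 0.00073 with a mean of at least 10 CPM, 0.0017 with the replicate block, 0.052 with ERCC scaling and 0.048 with ERCC scaling and the block, and -0.035 to 0.053 without 1 library. Bcl2l11 was 0.0034 with ERCC scaling and 0.012 with the block added. Brd3 was 0.019, 0.0030, 0.041 and 0.041 with library size, upper quartile, ERCC, and ERCC and block scaling, 0.021 without DMSO replicate 2 and JQ1 replicate 2, and -0.050 to 0.021 without 1 library. Cdk6 ran from -0.040 to 0.44 without 1 library. The cause was not tested. The 95% interval of the median gene reached 0.351 to either side, a spread that holds more than counting error, and the share due to depth was not tested.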

Other observations

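The tests of neighbouring genes were planned before their result was seen except that of divergent pairs, which was chosen after, and the shares by gene span and the noise of pseudogenes were tabulated after the data were seen.

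Protein-coding genes that span over 100 kb were lower after JQ1 in 23.1% of 978 cases, those of 30 to 100 kb in 19.5% of 2829, those of 10 to 30 kb in 15.4% of 3116, those of 3 to 10 kb in 14.5% of 1736 and those under 3 kb in 8.85% of 497. The shares of higher genes were 14.0%, 16.6%, 14.1%, 14.4% and 16.5% in the same order. After RG6146 the shares of lower genes were 21.1%, 16.8%, 13.4%, 13.4% and 7.85%. Processed pseudogenes were noisier than protein-coding genes of the same level. At 100 CPM or more, 15.3% of 118 processed pseudogenes and 0.781% of 1408 protein-coding genes had an SD of log2 CPM over 1, and at 10 to 100 CPM it was 24.5% of 319 and 0.444% of 5183.

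Neighbouring protein-coding genes may share local regulation, a hypothesis tested on pairs of neighbours. The log2 fold changes after JQ1 of 2708 pairs 5 to 50 kb apart were correlated with r = 0.0684 (permutation p = 2e-04, 10000 shuffles), a small value across genes that are not independent replicates. The 1155 opposite-strand pairs had r = 0.0988 (permutation p = 3e-04) and the 1553 same-strand pairs 0.0463 (permutation p = 0.031), which decides nothing on reads that run from 1 gene into the next, since the strand setting of the counts is unknown. Such reads would leave divergent pairs, whose transcripts run away from each other, uncorrelated, yet 650 of these had r = 0.0868 (permutation p = 0.014), and 505 convergent pairs had 0.112 (permutation p = 0.007). Pairs under 5 kb apart had r = 0.205 (permutation p = 1e-04, the smallest the shuffles can give) and pairs over 50 kb apart 0.0304 (permutation p = 0.037). After RG6146 the pairs 5 to 50 kb apart had r = 0.0659. Shared local regulation predicted a correlation above the shuffles, which was seen. But the shuffles moved fold changes among all protein-coding genes, so any other property that neighbours share, such as gene span, could also exceed them. The test therefore cannot tell shared local regulation from such properties. Reads on the opposite strand of overlapping genes stay open for the closest pairs.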
